A study of Mus musculus with 12 samples.

How the data were processed

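Polyadenylated RNA of inguinal white and of brown adipose tissue was measured by RNA sequencing in 12 mouse libraries, 3 in each of 4 groups: WAT control, WAT AKO, BAT control and BAT AKO. Groups and replicate numbers came from the sample titles. Per the labels' protocols, RNA was isolated with TRIzol and libraries were made with the VAHTS Universal V6 kit for Illumina. The labels number the libraries as replicates and do not say that each came from its own animal, so the p-values measure the spread between these libraries. The Cre driver, the floxed exon and the sex of the animals are not given in the sources used here.

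The deposited counts are whole numbers of reads per Ensembl gene and library, made by the authors and not normalised. Per the submitters' processing notes, the tools were Bowtie2 2.2.3, HISAT2 2.1.0 and HTSeq 0.6.0 with the genome build mm10. The role of each tool, the annotation release and the strand setting are not given in the sources used here. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart. Among others named in the text this touches Eif4a2 and Rfc4 (194 shared exon bases), Acot11 and Fam151a (1263), Gm7049 and Gm48795 (819), Foxp3 and Ccdc22 (590), Hmgcs1 and Gm48342 (557), and Icam1 and Gm47079 (511). The authors also deposited FPKM values. A check of counts against FPKM found them to be the counts divided by a constant per gene and by the library total, with a largest relative deviation of 1.38e-08 among genes with at least 20 counts, so they hold no further measurement. The FPKM table lists the 31231 genes with a count in at least 1 library. The count table lists 52550 gene IDs, of which 52403 had a symbol in the GENCODE M21 annotation of the same build and 147 had none. Coordinates come from that annotation.

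Total counts ran from 15692588 to 18967159 per library. Replicates of a group differed by more than sampling noise, with chi-square values per degree of freedom of 16.5 to 83.4, so each library was counted as 1 replicate. Intervals on counts and the floor of 3 counts cover counting error only, since reads without molecular identifiers are not independent molecules.

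Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F-test on counts with TMM normalisation. Genes passed filterByExpr with a minimum count of 10 and a minimum total of 15, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05 over all genes tested. AKO was compared with control within WAT and within BAT on 6 libraries each, BAT with WAT on the 6 control libraries, and the difference of the AKO effects on all 12 libraries. Levels are TMM-normalised counts scaled to library size (CPM), given as mean ± SD. TMM factors were taken over the libraries of each comparison, so the level of a gene in the same libraries can differ between comparisons. Levels of Cd79a are CPM of the library total without TMM, and those of the p53 targets use factors over all 12 libraries. Single values were compared by exact two-sided permutation tests. The overlap of calls was tested by Fisher's exact test. The 41 gene lists were tested per comparison with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 41 lists. A camera test with an estimated correlation and fry were run beside it.

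The design, the lists, the tests and a first set of alternatives were fixed before the data were examined. The rule for named genes took Mcu and its partners, Ucp1, Ppargc1a, Cidea, Adipoq, Lep and Pparg, and in each tissue the 10 largest called changes in each direction. These needed a mean of at least 2 CPM and separated groups, and predicted genes were left out. The rule also took up to 4 members with the smallest p from each list described. For the difference between tissues it took the 5 genes with the smallest p in each direction, and for BAT against WAT the 5 largest changes in each direction. A gene named outside this rule is said to be chosen after its values were seen, and some genes within it are not reported here.

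That first set held DESeq2's size factors in edgeR (RLE), no filter, a filter of at least 2 CPM, DESeq2 1.42.0, limma voom, limma on log2 FPKM with a pseudocount of 1 or 0.1 or with a mean FPKM of at least 1, the replicate number as a block, each library left out in turn, all 12 libraries in 1 fit, a 2-fold threshold and an adjusted p under 0.1. The alternatives chosen after seeing the data were a robust fit, a muscle marker covariate, leaving out the libraries with most muscle counts, a B lymphocyte marker covariate, and control 2 as the only WAT control. The libraries with most muscle counts were taken within each group: WAT control 1, WAT AKO 2, BAT control 1 and BAT AKO 2. WAT control 2 (0.434% muscle counts) held a larger share than BAT control 1 (0.248%) but was kept. With control 2 as the only WAT control that group holds 1 library, so the spread comes from the other groups alone. The lymphocyte covariate was first also fitted to BAT against WAT and then dropped there, because lymphocyte markers are near absent from BAT and the covariate stood for the tissue.

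Across tissues, libraries with the same number and genotype deviated together from their group means. The correlations were 0.517, 0.23 and 0.45 for controls and 0.569, 0.677 and 0.14 for AKO, all above 0.1. WAT AKO 3 correlated better with BAT AKO 1 than with BAT AKO 3, and the other 5 WAT libraries best with the library of their own number. The numbers were therefore treated as pairing WAT and BAT of 1 animal in the fits with a block and in some splits of the libraries. The main fits of the tissue difference and of BAT against WAT left this pairing out, so their p-values and SE ignore it. This pairing comes from the data and not from the labels, and muscle counts were high in libraries with the same number in both tissues. Within a tissue, control and AKO libraries share only a number. Those of number 3 also passed 0.1, with 0.226 in WAT and 0.117 in BAT, so that bound alone does not mark a pair.

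The tests were tested on simulated data, negative binomial counts drawn from these libraries' means and dispersions, with 67, 67 and 66 genes changed by 1.5, 2 and 4-fold. In the WAT comparison, on 15571 genes, edgeR recovered 1.49%, 17.9% and 83.3% of them, with 7 false calls among 75. DESeq2 on the same simulation, with 15915 genes, recovered 14.9%, 53.7% and 92.4%, with 46 false calls among 153. In the BAT comparison, on 14054 genes, edgeR recovered 1.49%, 38.8% and 92.4%, with 9 false among 97 calls. For the difference between tissues, on 16144 genes, it recovered 1.49%, 22.4% and 77.3%. For BAT against WAT, on 14765 genes, it recovered 0%, 29.9% and 80.3%. Changes of 1.5-fold were therefore mostly out of reach in each comparison. A simulated 1.5-fold change of the complex I list was called in all 4 comparisons. Simulated genes were drawn independently. In the data the members of that list had estimated correlations from 0.467 in BAT to 0.738 for BAT against WAT. The simulation therefore does not test the list calls under such correlation.

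Processed pseudogene transcripts were matched to protein-coding transcripts of GENCODE M21 with BLAST+ 2.17.0 at an e-value of at most 1e-20. Lists of p53 targets and of liver transcripts were added for the closing section, the first after some of its members had been seen.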

Results

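RNA from inguinal white adipose tissue (WAT) and brown adipose tissue (BAT) of mice was measured in 12 libraries, 3 for each of 4 groups. The controls were Mcu fl/fl mice, which carry a floxed Mcu gene. The AKO mice were Mcu fl/fl animals in which Mcu, the pore-forming subunit of the mitochondrial calcium uniporter, had been removed in adipose tissue. The series' design text places both genotypes on a high-fat diet and asks how their expression profiles differ in white and brown fat. Total gene counts ran from 15692588 to 18967159 per library. Scd1, a fatty acid desaturase, was the most abundant transcript of every WAT library, and mt-Co1, a cytochrome oxidase subunit encoded by the mitochondrial genome, of every BAT library.

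Some libraries held transcripts of other tissues. Skeletal muscle genes took 1.66% of counts in WAT control 1, 2.95% in WAT AKO 2 and 2.34% in BAT AKO 2, against 0.434% or less in each of the other 9 libraries. Cd79a, a B cell receptor component, reached 173, 123 and 307 CPM (counts scaled to the library total, without TMM normalisation) in the WAT AKO libraries and 106 in WAT control 2. It lay at 0.949 and 0.339 CPM in WAT controls 1 and 3. Both measures are plotted per library.

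**Figure D1:**
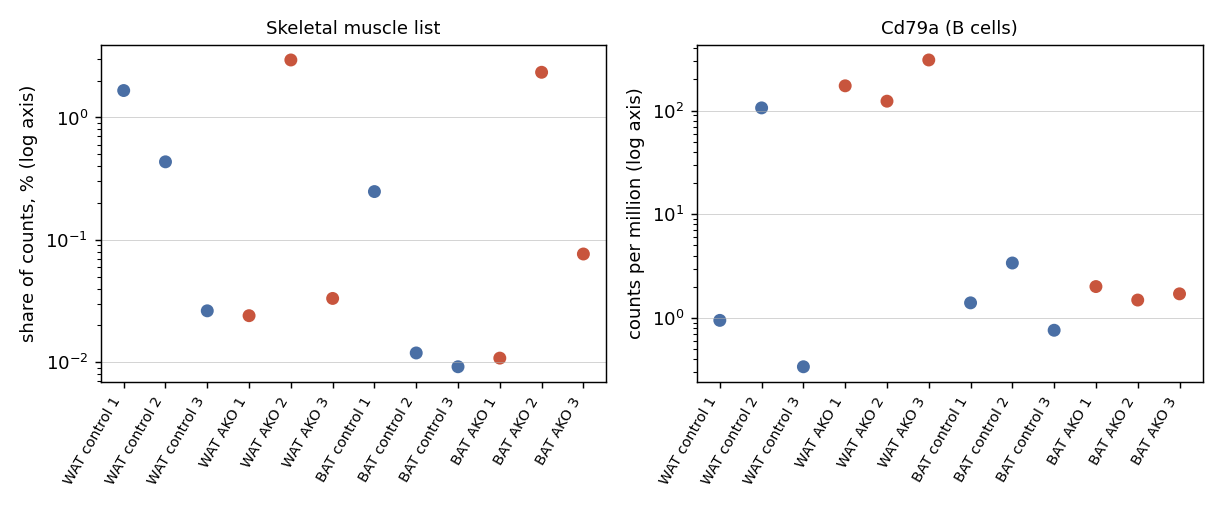
Skeletal muscle transcripts as a share of each library's counts (left, percent, log axis) and Cd79a (right, CPM, log axis) in the 12 libraries, with controls in blue and AKO in red. Muscle counts were highest in WAT AKO 2 at 2.95%, and Cd79a was above 100 CPM in the 3 WAT AKO libraries and WAT control 2.

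Mcu, the targeted gene, lies on the minus strand of chromosome 10 (59446984 to 59616692, mm10) and was lower in every AKO library than in every control library of its tissue. In WAT it measured 21.7 ± 0.652 CPM in controls and 12.9 ± 1.5 CPM in AKO (SD, n = 3 each), or 59.5% of the control mean. In BAT it measured 22.6 ± 1.94 CPM in controls and 9.38 ± 3.08 CPM in AKO (SD, n = 3 each), or 41.5%. The log2 fold changes were −0.75 in WAT (95% interval −1.05 to −0.45) and −1.27 in BAT (95% interval −1.79 to −0.75). The exact two-sided permutation test gave p = 0.1 in each tissue, the smallest p that 3 against 3 libraries allow. In edgeR's test over all genes, Mcu missed the 0.05 threshold in WAT (adjusted p = 0.0799) and in BAT (adjusted p = 0.202). DESeq2 called it in WAT (adjusted p = 0.000558) and BAT (adjusted p = 1.51e-05), a fit of all 12 libraries in both (adjusted p = 0.0435 and 0.049), and edgeR without WAT control 2 in WAT (adjusted p = 0.037). Over all alternatives its adjusted p ranged from 0.000558 to 0.368 in WAT and from 1.51e-05 to 0.552 in BAT. The counts cover whole genes, so reads from exons outside the deleted part remain included, and the labels do not state which exon is floxed. The libraries were made from adipose tissue, and how much Mcu RNA each cell type contributed was not measured.

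**Figure D2:**
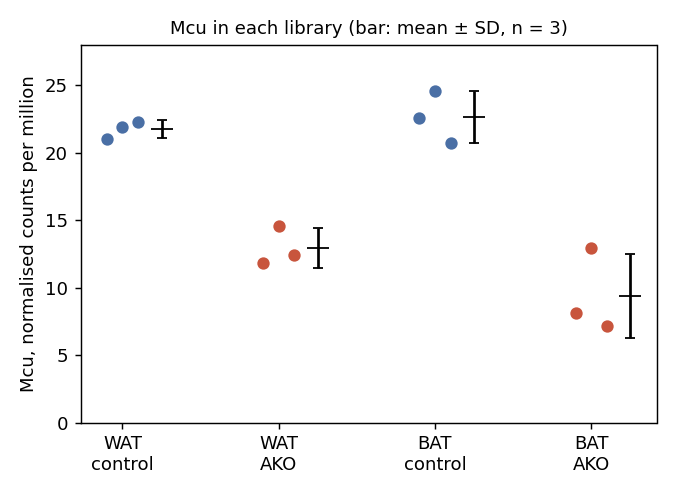
Mcu in TMM-normalised CPM for each of the 12 libraries (points), with the mean and SD of each group of 3 (bars). The WAT AKO libraries sit between 11.8 and 14.6 CPM and the WAT controls between 21 and 22.3. The BAT AKO libraries sit between 7.12 and 12.9 CPM and the BAT controls between 20.7 and 24.6.

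The partners of Mcu in the uniporter complex given here showed no change that passed the test in either tissue. Mcub, a paralogous subunit that lowers uniporter activity, had a log2 fold change of −0.72 in WAT (SE 0.23, adjusted p = 0.154) and −0.40 in BAT (SE 0.297, adjusted p = 0.57). Micu2 measured −0.10 in WAT and 0.01 in BAT, Micu3 −0.12 and 0.22, Smdt1 (the EMRE subunit) −0.12 and −0.09, and Mcur1 −0.29 and 0.20.

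In WAT, the comparison of AKO with control asked which transcripts differ in white fat of AKO mice, where Mcu stood at 59.5% of its control level. Zfp949, a zinc finger protein gene, rose from 12.5 ± 1.37 to 47.2 ± 6.2 CPM (log2 fold change 1.92, SE 0.146, adjusted p = 0.0403). Gm8210 and Gm11868, processed pseudogenes named here because they complete a count of 3, also rose (log2 5.87, SE 0.246, and 4.05, SE 0.317). Both were chosen after their values were seen. Gm8210 is 99.38% identical to Rpl29 and Gm11868 97.98% identical to Cyb5r4, so their reads cannot be assigned with certainty. Zfp949 lies on chromosome 9 (88548020 to 88571061), in the same stretch as Rpl29 and Cyb5r4. A strain variant of this stretch in AKO mice is weighed in the closing section and was left open. Leptin (Lep), the adipocyte satiety hormone, measured 1840 ± 553 CPM in AKO against 3810 ± 1350 in controls (log2 −1.05, SE 0.343, adjusted p = 0.159). Adiponectin (Adipoq) measured −0.40, the adipogenic factor Pparg −0.26, the lipid droplet protein Cidea 0.50 and the coactivator Ppargc1a 0.28 on the log2 scale, with no adjusted p under 0.254. Ucp1, the uncoupling protein of thermogenic fat, did not pass the count filter in WAT. It had 0.239 ± 0.232 CPM in controls and 5.18 ± 5.36 in AKO (SD, n = 3 each, exact permutation p = 0.2). Its counts were 5, 0 and 9 in the controls and 255, 9 and 89 in AKO, so the AKO libraries differed widely. In the edgeR fit with no filter it had a log2 fold change of 4.39 (SE 1.11, adjusted p = 0.102). These 3 genes were all that passed of 15915 tested, with 0 lower by edgeR. Without a correction for multiple tests, 1683 genes were higher and 1914 lower at p under 0.05, where 796 in all are given by chance. DESeq2 called 660 higher and 958 lower, and limma voom 1 and 0. The groups did not overlap for 30.7% of genes, against 10% by chance. Leaving out control 2 raised the count from 3 to 1649 (1066 higher and 583 lower), and leaving out control 1, control 3 or any AKO library reduced it to 1. Gm8210 was called in each of these 6 fits, while Zfp949 had adjusted p of 0.127, 0.107, 0.262, 0.0915 and 0.19 without control 1, control 3, AKO 1, AKO 2 and AKO 3, and Gm11868 of 0.127, 0.107, 0.262, 0.126 and 0.218.

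Lists of genes fixed in advance were tested in WAT. Of 28 measured extracellular matrix genes, 27 had negative log2 fold changes, with a median of −0.87 (camera adjusted p = 2.07e-09; adjusted p = 0.812 with an estimated correlation). None passed over all genes, and 18 were lower when adjusted over the list alone. Among them were Col6a3 (−1.04, SE 0.174), Col5a1 (−0.95, SE 0.17) and Col5a2 (−1.03, SE 0.194), which encode collagen chains, and Loxl1 (−0.87, SE 0.158), a collagen and elastin crosslinking enzyme. Of 27 macrophage genes, 24 were negative, with a median of −0.62 (camera adjusted p = 9.7e-08; adjusted p = 0.812 with an estimated correlation). Adjusted over the list alone, 14 were lower and 1 higher, with Lgals3 at −1.32, Trem2, a receptor of lipid-associated macrophages, at −2.34, the lysosomal proton pump subunit Atp6v0d2 at −2.51 and Adgre1, the F4/80 antigen, at −1.33. Of 23 cholesterol synthesis genes, 20 were negative and 16 were lower when adjusted over the list alone, with a median of −0.73 (camera adjusted p = 5.81e-07; adjusted p = 0.812 with an estimated correlation). Insig1, which retains the sterol sensor in the endoplasmic reticulum, measured −1.75 (SE 0.235), mevalonate kinase Mvk −0.57 and the sterol desaturase Sc5d −0.84.

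Lists for fatty acid uptake and for triglyceride synthesis and lipid droplets were also lower in AKO WAT, while those for de novo lipogenesis, lipolysis and fatty acid oxidation were not called (camera adjusted p = 0.112, 0.144 and 0.144). Fatty acid uptake genes had a median of −0.50, with 12 of 13 negative and 2 lower when adjusted over the list alone (camera adjusted p = 0.00167; adjusted p = 0.812 with an estimated correlation). The fatty acid binding protein Fabp5 measured −0.94 (SE 0.127) and the fatty acid transporter Slc27a4 −0.49 (SE 0.105). Triglyceride synthesis and lipid droplet genes had a median of −0.28, with 13 of 20 negative (camera adjusted p = 0.00738; adjusted p = 0.926 with an estimated correlation). Adjusted over the list alone, 7 were lower and 1 higher. Plin2, a lipid droplet coat protein, measured −1.20, and Agpat2, Dgat2 and Gpd1, enzymes of glycerolipid synthesis, −1.25, −1.10 and −0.85. All 16 endothelial genes were negative, with a median of −0.49 and none called over all genes or adjusted over the list alone (camera adjusted p = 0.0196; adjusted p = 0.939 with an estimated correlation). The endothelial list was not called without control 3 (median −0.07, adjusted p = 0.229) or AKO 2 (median −0.37, adjusted p = 0.139), and the triglyceride list not without control 1 (adjusted p = 0.0936). The median of the triglyceride list was −0.17 without control 2 and −0.19 without AKO 1.

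Lymphocyte lists were higher in AKO WAT. B lymphocyte genes had a median of 2.50, with 15 of 16 positive (camera adjusted p = 3.3e-05; adjusted p = 0.926 with an estimated correlation). T and NK lymphocyte genes had a median of 1.37, with 20 of 20 positive (camera adjusted p = 0.000129; adjusted p = 0.926 with an estimated correlation). No member of either list was called over all genes or adjusted over the list alone. Without control 2, the WAT control that held lymphocyte transcripts, the medians were 6.72 for B and 3.97 for T and NK lymphocytes. Against control 2 alone, a control group of 1 library, they were 1.01 and 0.30. Jchain, the joining chain of polymeric antibodies, measured 2.46 (SE 0.71) and Foxp3, the regulatory T cell factor, 2.29 (SE 1.02). Genes of respiratory complex I had a median of −0.03 (camera adjusted p = 0.531), and thermogenic genes a median of 0.10 (camera adjusted p = 0.996). In all, 8 of 41 lists were called in WAT, none of them with an estimated correlation. Of the 10 splits of the WAT libraries into groups of 3, the real one included, 8 called at least 8 lists. Another split called up to 23. Lymphocyte transcripts were highest in the 3 AKO libraries and control 2, which is what the lymphocyte lists measure and no separate result. WAT AKO 2 and control 1 held most muscle counts.

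**Figure D3:**
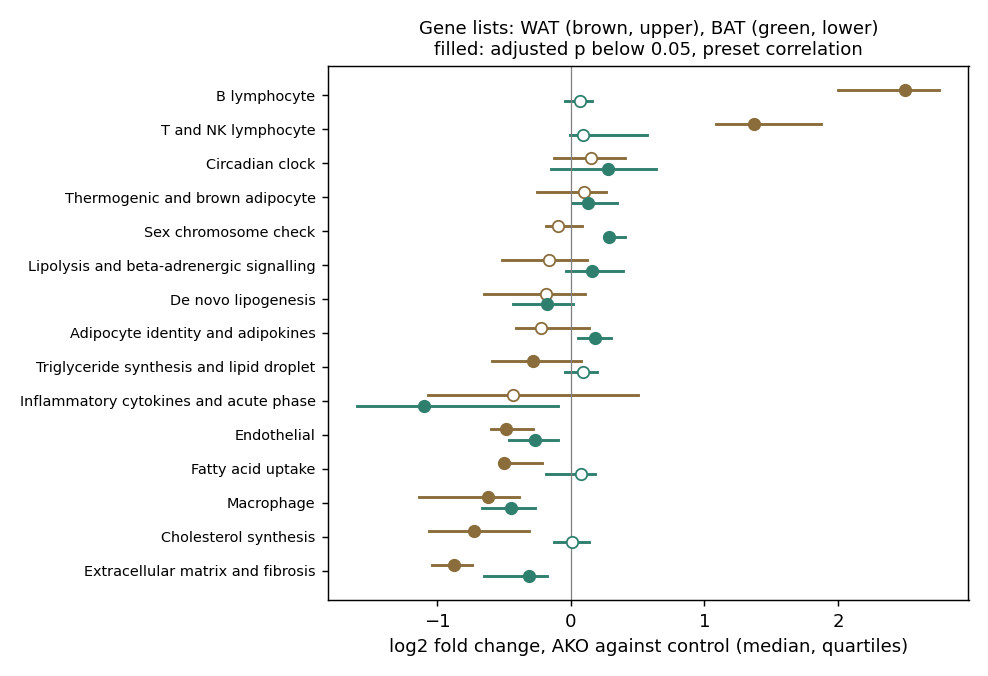
Median log2 fold change of AKO against control (points) with the quartiles over each list's members (lines), for 15 gene lists called in WAT (brown) or BAT (green), without the skeletal muscle list. Filled points mark an adjusted p under 0.05 with the preset correlation; extracellular matrix genes had a median of −0.87 in WAT and −0.31 in BAT.

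In BAT, the same comparison was made in brown fat. Kng1, which encodes the kinin precursor kininogen, rose from 0.145 ± 0.0379 to 15.1 ± 4.45 CPM (log2 fold change 6.63, SE 0.35, adjusted p = 0.00284; SD, n = 3 each). The Krüppel-like transcription factor genes Klf11 and Klf10 rose 2.24-fold (SE 0.0776 on the log2 scale, adjusted p = 0.0074) and 1.98-fold (SE 0.111, adjusted p = 0.0485). Pth1r, the receptor of parathyroid hormone and its related peptide, fell from 45.8 ± 3.58 to 19 ± 2.38 CPM (log2 −1.27, SE 0.116). Trib1, a pseudokinase that directs protein degradation, fell from 98.2 ± 10.1 to 40 ± 5.03 CPM (log2 −1.30, SE 0.122). Rspo4, a secreted enhancer of Wnt signalling, fell from 8.33 ± 0.461 to 2.26 ± 0.406 CPM (log2 −1.88, SE 0.184). Rpl29, a protein of the large ribosomal subunit, measured 44.6 ± 3.84 CPM against 91.3 ± 4.57 (log2 −1.04, SE 0.0921). The adjusted p of these 4 genes lay between 0.0267 and 0.0271 in edgeR's test. Kng1 was not called without control 3 (adjusted p = 0.0587) or AKO 3 (adjusted p = 0.0504), and the other 6 were called only in the fit without control 2. Without control 1, control 3, AKO 1, AKO 2 or AKO 3 their adjusted p ran from 0.0604 to 0.118 for Klf11, 0.0787 to 0.292 for Klf10, 0.0821 to 0.181 for Pth1r, 0.0787 to 0.24 for Trib1, 0.0787 to 0.247 for Rspo4 and 0.0824 to 0.128 for Rpl29.

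Of 14265 genes tested in BAT, 11 passed, 7 higher and 4 lower. The remaining 4 were processed pseudogenes that rose. Tma7-ps (log2 1.56, SE 0.14) meets the rule for named genes, and Gm8210 (5.62, SE 0.585), Gm11868 (4.32, SE 0.417) and Gm7049 were chosen after their values were seen. Gm7049 had 73 counts over the AKO libraries and 3 over the controls, a ratio of 24.2 (95% counting interval 7.98 to 120). Gm8210 and Rpl29 share near-identical sequence. Gm8210 rose from 0.0811 ± 0.0915 to 4.43 ± 1.38 CPM, far less than Rpl29 fell (91.3 to 44.6 CPM). Reads counted for Gm8210 therefore do not account for the fall of Rpl29. How reads that match both were counted is not given, so the fall stays uncertain. Without a correction for multiple tests, 998 genes were higher and 944 lower, where 713 in all are given by chance, and DESeq2 called 131 higher and 134 lower. Leaving out control 2 gave 95 calls, control 1 gave 2, AKO 1 and AKO 2 gave 1 each, and control 3 and AKO 3 gave 0. The 4 pseudogenes were called only without control 2, with adjusted p of 0.0787 to 0.383 in the 5 other fits. Gm8210 had a log2 of 6.82 without control 2, and Gm11868 of 5.003 without control 3. The groups did not overlap for 20% of genes, against 10% by chance.

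Of the genes of brown fat function, none passed the test over all genes in BAT. Ucp1 measured 3820 ± 518 CPM in AKO and 3400 ± 337 in controls (log2 0.17, SE 0.118, adjusted p = 0.545). Ppargc1a, a coactivator of mitochondrial biogenesis, measured 36.8 ± 9.42 against 23.7 ± 1.34 CPM (log2 0.63, SE 0.175, adjusted p = 0.27), and Cidea, Adipoq and Pparg measured 0.21, 0.18 and 0.04 on the log2 scale. Lep measured −1.04 (SE 0.474, adjusted p = 0.391). Thermogenic genes had a median of 0.13 with 21 of 28 positive (camera adjusted p = 0.0397; adjusted p = 0.802 with an estimated correlation), and none passed over all genes or adjusted over the list alone. The list was not called without control 2, control 3, AKO 1 or AKO 3 (adjusted p = 0.198, 0.189, 0.156 and 0.436), and its median was 0.23 without AKO 2 and 0.05 without AKO 3. Among its members Ebf2 measured 0.57 and Slc29a1, an adenosine transporter, 0.74, while the thioesterase Acot11 measured −0.35. The widest values, named after they were seen, were 1.17 for the nuclear receptor Esrrg (SE 0.365, adjusted p = 0.293) and −1.31 for the deiodinase Dio2 (SE 0.651, adjusted p = 0.418). Genes of respiratory complex I had a median of 0.03 (camera adjusted p = 0.406).

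The macrophage, inflammatory, matrix and endothelial lists were lower in AKO BAT. The macrophage list had a median of −0.45 with 22 of 26 negative and 2 lower when adjusted over the list alone (camera adjusted p = 3.12e-05; adjusted p = 0.477 with an estimated correlation). Cd14, the endotoxin coreceptor, measured −0.90 and the integrin Itgam −1.21. Inflammatory genes had a median of −1.10 with 17 of 21 negative and 7 lower when adjusted over the list alone (camera adjusted p = 0.000979; adjusted p = 0.477 with an estimated correlation). The monocyte chemokines Ccl7 and Ccl2 measured −4.18 (SE 0.681) and −3.25 (SE 0.795), and the adhesion molecule Icam1 −1.40 (SE 0.233). Extracellular matrix genes had a median of −0.31 with 25 of 28 negative and none lower when adjusted over the list alone (camera adjusted p = 0.000101; adjusted p = 0.477 with an estimated correlation). Among them Col4a2 and Col4a1, basement membrane collagens, measured −0.63 each. Endothelial genes had a median of −0.27 with 13 of 16 negative, and Sox18 and Mmrn2 were lower when adjusted over the list alone, at −0.61 each (camera adjusted p = 0.00481; adjusted p = 0.802 with an estimated correlation). The endothelial list was not called without AKO 3 (adjusted p = 0.0639).

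The circadian clock list was higher in AKO BAT, with a median of 0.28 and 12 of 17 positive (camera adjusted p = 0.00666; adjusted p = 0.477 with an estimated correlation). Adjusted over the list alone, 7 were higher, among them the repressors Nr1d2 (0.88, SE 0.11), Ciart (0.81), Per3 (0.86) and Per2 (0.60), and 1 was lower. Adipocyte identity genes had a median of 0.18, with Nrg4 at 0.43 and Nnat at 0.65 (camera adjusted p = 0.0217; adjusted p = 0.477 with an estimated correlation). Lipolysis genes had a median of 0.16, with the prostaglandin receptor Ptger3 at 0.46 and the phosphodiesterase Pde3b at 0.53 (camera adjusted p = 0.0335; adjusted p = 0.613 with an estimated correlation). De novo lipogenesis genes had a median of −0.18, with the NADPH-producing enzymes Pgd and Me1 at −0.43 and −0.49 (camera adjusted p = 0.032; adjusted p = 0.802 with an estimated correlation). The 4 Y-linked genes of the sex chromosome list had a median of 0.29 (camera adjusted p = 0.0163; adjusted p = 0.477 with an estimated correlation). All 12 libraries of both tissues held the Y-linked Ddx3y, with 396 to 1327 counts. The female transcript Xist had 0 to 14 counts, so by these genes the groups did not differ in sex. Skeletal muscle genes had a median of 3.33 (camera adjusted p = 0.0451; adjusted p = 0.853 with an estimated correlation), which became −1.19 without AKO 2, the BAT library with 2.34% muscle counts. In all, 11 of 41 lists were called in BAT, none of them with an estimated correlation. Of the 10 splits of the BAT libraries into groups of 3, the real one included, 3 called at least 11 lists. Another split called up to 12. Leaving out AKO 3 gave 5 called lists and leaving out control 2 gave 7. Without control 2 the lists for sex chromosomes, adipocyte identity, lipogenesis, lipolysis and muscle had adjusted p of 0.12, 0.0745, 0.395, 0.069 and 0.347, and without AKO 3 all of these but adipocyte identity had 0.0541, 0.137, 0.0688 and 0.082. Adipocyte identity and lipolysis were not called without AKO 1 (adjusted p = 0.072 and 0.0997), lipolysis and muscle not without control 3 (0.132 and 0.494), and lipogenesis and muscle not without AKO 2 (0.0905 and 0.788). Medians moved without control 2 to 0.46 for the clock, 0.28 for lipolysis and −0.11 for lipogenesis, which had −0.32 without AKO 1 and −0.11 without AKO 2, and to 8.87 for muscle without control 1.

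Whether the AKO effect differed between the tissues was tested as the BAT effect minus the WAT effect. Klf11 was called with a difference of 1.39 (SE 0.111, adjusted p = 0.0014), from log2 fold changes of −0.26 in WAT and 1.16 in BAT. Differences above 0 were also called for Agpat2 (1.66, SE 0.212), the lysosomal acid lipase Lipa (1.23, SE 0.154), the endosomal ferrireductase Steap3 (1.29, SE 0.162) and the keratin Krt79 (1.61, SE 0.21), with adjusted p of 0.0228 to 0.023 in edgeR's test. In WAT these 4 genes measured −1.25, −0.86, −0.94 and −1.46, and in BAT 0.45, 0.41, 0.39 and 0.19. The largest calls below 0 by p were Ier5, an immediate early response gene (−2.79, SE 0.241, adjusted p = 0.0015), and Snhg15, a long noncoding RNA (−2.97, SE 0.372, adjusted p = 0.0228). Aaas, a nuclear pore protein gene, measured −2.19 (SE 0.308), Bbc3, which encodes the apoptosis inducer PUMA, −2.49 (SE 0.353), and Icam1 −2.23 (SE 0.322), each with an adjusted p of 0.0262. In WAT these 5 genes had log2 fold changes of 1.63, 2.17, 1.56, 1.63 and 0.79, and in BAT of −1.12, −0.75, −0.58, −0.81 and −1.40.

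**Figure D4:**
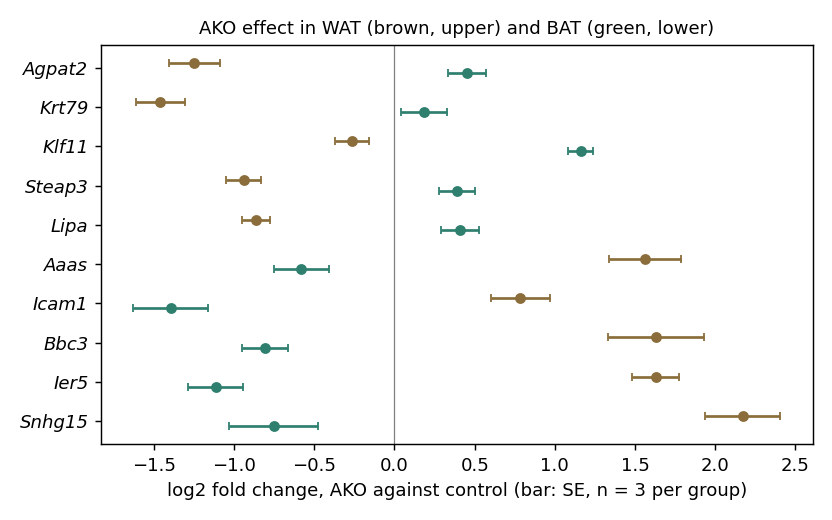
Log2 fold change of AKO against control in WAT (brown) and BAT (green) with standard errors (n = 3 per group) for the 10 named genes whose effect differed between the tissues. Ier5 had 1.63 in WAT and −1.12 in BAT, and Klf11 −0.26 and 1.16.

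In all, 45 of 16391 genes had a different effect in the 2 tissues, 25 with a difference above 0 and 20 below. With the animal as a block, 261 genes were called (106 above and 155 below 0), among them 44 of the 45. With the deposited FPKM values in place of counts the split was 25 above against 74 below 0 with a pseudocount of 1, 21 against 65 with 0.1, and 31 against 81 among genes with a mean FPKM of at least 1. FPKM is scaled without TMM, and the median difference of all genes was −0.11, −0.16 and −0.12 there, against −0.02 with counts. Leaving out WAT control 2 gave 923 calls, BAT control 2 gave 135 and WAT AKO 2 gave 107. Leaving out WAT control 3, BAT AKO 2, BAT control 1 and BAT AKO 3 gave 12, 11, 5 and 4, and WAT AKO 1, WAT AKO 3, BAT control 3 and BAT AKO 1 gave 2 each. WAT control 1 gave 35. Klf11 and Ier5 were called in each of these 12 fits. Lipa, Steap3, Agpat2, Krt79, Snhg15, Aaas, Bbc3 and Icam1 were not called without WAT AKO 1, WAT AKO 3, BAT control 1, BAT control 3 or BAT AKO 1, nor, Snhg15 apart, without BAT AKO 3, with adjusted p of 0.0508 to 0.0861. Krt79, Aaas and Icam1 were also not called without WAT control 3 (adjusted p = 0.0519, 0.0543 and 0.0658), nor Aaas and Bbc3 without BAT AKO 2 (adjusted p = 0.072 and 0.0722). None of the 45 was called without WAT control 1, WAT AKO 2, BAT control 1 and BAT AKO 2, the library of each group with most muscle counts. That fit had 2 libraries per group.

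By list, the difference lay above 0 for 9 lists and below 0 for 2. Cholesterol synthesis had a median difference of 0.45, with 19 of 23 genes positive and 11 higher when adjusted over the list alone (camera adjusted p = 9.44e-06; adjusted p = 0.553 with an estimated correlation). Insig1 was called over all genes (2.84, SE 0.419, adjusted p = 0.0275) and Hmgcs1, which makes HMG-CoA, measured 1.82 (SE 0.359). Triglyceride synthesis and lipid droplet genes had a median difference of 0.43 with Agpat2 and Dgat2 called over all genes (camera adjusted p = 0.00201; adjusted p = 0.553 with an estimated correlation). Extracellular matrix and fatty acid uptake genes had median differences of 0.40 and 0.42, each with a camera adjusted p of 0.00201 and an adjusted p of 0.553 with an estimated correlation. B lymphocyte genes had a median difference of −2.54 (camera adjusted p = 0.000464; adjusted p = 0.71 with an estimated correlation) and T and NK lymphocyte genes of −1.06 (camera adjusted p = 0.00679; adjusted p = 0.78 with an estimated correlation). Lymphocyte transcripts were near absent from BAT, with Cd79a at 0.762 to 3.39 CPM without TMM. Without WAT control 2 the medians were −7.03 for B and −3.22 for T and NK lymphocytes, and without BAT control 2 −0.70 and −0.45, where the T and NK list was not called (adjusted p = 0.0991). The matrix median was 0.63 without BAT control 3, and with control 2 as the only WAT control 4 lists were called.

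The overlap of the calls in WAT and BAT was counted among 13851 genes tested in both. Gm8210 and Gm11868 were higher in both tissues, against 0.0013 shared genes for independent lists (Fisher's exact p = 4.69e-07), and 0 genes were called lower in both. At an unadjusted p under 0.05, 92 genes were higher in both against 94.3 for independent lists (Fisher's exact p = 0.866), and 181 were lower in both against 120 (Fisher's exact p = 4.56e-09). Of 491 genes at that p in both tissues, 273 (55.6%) went in the same direction. Since WAT and BAT libraries of 1 number deviate together, differences between animals also enter these overlaps, and independent lists are no full reference for them. DESeq2 gave 10 shared higher genes and 24 shared lower genes, against 4.33 and 9.27. Among the 10 were Zfp949, the clock gene Per3 and the translation initiation factor Eif4a2, and among the 24 were the chemokines Ccl6 and Ccl9 and the collagens Col4a1 and Col4a2, named after their values were seen. Across genes, which are not independent replicates, the log2 fold changes of the tissues had a Pearson r of 0.10 and a Spearman rho of 0.05. The 2 shared calls became 5 without WAT control 2, stayed 2 without BAT control 2, were 1 without any other WAT library and were 0 without any other BAT library.

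BAT and WAT of control mice were compared as background for the tissues, with CPM normalised over the 6 control libraries. Ucp1 measured 3910 ± 406 CPM in BAT and 0.232 ± 0.224 CPM in WAT (log2 14.02, SE 0.713, adjusted p = 4.88e-05; SD, n = 3 each). Lgr6, a receptor of R-spondins, was higher in BAT by a ratio of 6400 (95% counting interval 1770 to 52800), and Ptgds, a prostaglandin D synthase, by 1120 (381 to 5420). Rspo4 was at least 196-fold higher in BAT, against a floor of 3 counts over the WAT group, and the kininogen gene Kng2 660-fold higher. Higher in WAT were Hoxa10 by at least 189-fold, against a floor of 3 counts over the BAT group, Hoxc9 by a ratio of 790 (142 to 31200) and Hoxc10 by 756 (135 to 29900). Pramef12 was at least 65.5-fold and the leukocyte integrin Itgad 235-fold higher in WAT. With so few counts on the lower side, fitted log2 values moved to 14.89 for Ucp1 and −8.70 for Pramef12 without WAT control 3, to −11.39 for Hoxc9 and −10.25 for Itgad without BAT control 3, and to −11.32 for Hoxc10 without BAT control 2. In all, 3666 genes were higher and 3858 lower in BAT among 15031 tested, and the groups did not overlap for 61.4% of genes, against 10% by chance.

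Lists for the respiratory complexes, thermogenesis and fatty acid oxidation stood higher in BAT. All 37 complex I genes passed over all genes, with a median of 2.33 (camera adjusted p = 7.16e-20; adjusted p = 0.451 with an estimated correlation), and all 25 genes of complexes II to IV, with a median of 2.60 (camera adjusted p = 9.76e-16; adjusted p = 0.451 with an estimated correlation). Thermogenic genes had a median of 3.95 with 27 of 30 called higher and 1 lower (camera adjusted p = 8.66e-11; adjusted p = 0.415 with an estimated correlation). Fatty acid oxidation genes had a median of 2.44, with the trifunctional protein subunits Hadha and Hadhb at 3.58 and 4.08 (camera adjusted p = 1.38e-08; adjusted p = 0.451 with an estimated correlation). Macrophage genes were lower in BAT, with 27 of 27 called and a median of −2.11 (camera adjusted p = 7.23e-10; adjusted p = 0.415 with an estimated correlation), as were matrix genes, with 18 of 28 called and a median of −2.20 (camera adjusted p = 1.99e-07; adjusted p = 0.415 with an estimated correlation). In all, 22 of 41 lists were called, none of them with an estimated correlation. From FPKM the split of genes was 2050 higher and 5342 lower with a pseudocount of 1, 2074 and 5688 with 0.1, and 1916 and 4992 among genes with a mean FPKM of at least 1. FPKM is scaled by the library total without TMM. The median log2 fold change of all genes was −0.25, −0.37 and −0.28 in these fits, against −0.04 with counts. These splits therefore do not show that more genes are lower in BAT.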

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

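The tests chosen only after the result was seen were those of the adipocyte, cholesterol and other lists against dilution and against a loss of macrophages and matrix cells, and the fits of the lists with 1 library left out. Except for the macrophage list, each result here was set apart because the AKO effect differed between WAT and BAT in a test of the difference itself. The macrophage list was not called for the difference (camera adjusted p = 0.157) and was lower in both tissues. It is weighed here beside the matrix list. The differences, as BAT effect minus WAT effect in log2, were 1.39 for Klf11, 1.23 for Lipa, 1.29 for Steap3, 1.66 for Agpat2 and 1.61 for Krt79. They were −2.79 for Ier5, −2.97 for Snhg15, −2.19 for Aaas, −2.49 for Bbc3 and −2.23 for Icam1. With WAT and BAT of an animal kept together there are 10 splits, too few for a share under 0.05, and 1 of them, the real one, called as many genes, with 45 called and at most 0 in the others. Splits that part the tissues of an animal called up to 11.

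The median differences of the lists were 0.45 for cholesterol synthesis, 0.43 for triglyceride synthesis and lipid droplets, 0.42 for fatty acid uptake, 0.40 for extracellular matrix, 0.25 for adipocyte identity, 0.21 for lipolysis and 0.17 for fatty acid oxidation. They were 0.62 for vascular smooth muscle, 0.63 for the creatine cycle, −2.54 for B lymphocytes and −1.06 for T and NK lymphocytes. None of these 11 lists was called with an estimated correlation (adjusted p = 0.553 to 0.78 with an estimated correlation), and fry called 0. Of the 10 splits that keep animals together, 5 called at least the 11 lists of the real one, with up to 21 in another, and again they are too few for a share under 0.05. Without WAT control 1 the lists for lipolysis, adipocyte identity and fatty acid oxidation had adjusted p of 0.0953, 0.0884 and 0.418 by camera, and the median of the last was 0.06. Medians moved without WAT control 3 to 0.33 for lipolysis, 0.44 for adipocyte identity and 0.27 for the vascular list, without WAT AKO 2 to 0.33 for lipolysis, without BAT control 3 to 0.63 for the matrix, and without BAT AKO 3 to 0.11 for fatty acid oxidation. Without WAT control 2 and BAT control 2 they were −7.03 and −0.70 for B lymphocytes and −3.22 and −0.45 for T and NK lymphocytes. The vascular list had 0.118 without WAT control 3, and fatty acid oxidation 0.0559, 0.109 and 0.1 without WAT AKO 1, BAT control 3 and BAT AKO 3. The creatine cycle list was not called without WAT control 1 or 2, WAT AKO 1 or 3, BAT control 3 or BAT AKO 2, with adjusted p of 0.0583 to 0.11 and a median of 0.41 without the last.

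The lower matrix and macrophage lists in WAT were weighed by another measure than the fitted medians, the median difference of a list in mean log2 CPM, at −0.87 for the matrix (−1.06 to −0.71 against single controls), −0.60 for macrophages (−0.81 to −0.46) and −0.21 for adipocyte identity (−0.29 to 0.04). RNA of a lymph node, 1 possible source of the lymphocyte transcripts, could dilute the lists but would lower adipocyte identity alike. Against control 2 alone, the matrix list had −0.47, −0.55 and −0.94 in AKO 1, AKO 2 and AKO 3. Macrophages had −0.43, −0.49 and −0.56 there and adipocyte identity −0.33, −0.03 and −0.20, so in AKO 1 these lists lay close together. That comparison decides less, since the AKO libraries held more B lymphocyte transcripts than control 2 (0.84, 0.40 and 1.56). Without the pair of WAT libraries with most muscle counts the matrix median was −0.75, which argues against muscle RNA. A loss of macrophages and matrix cells alone is spoken against by cholesterol synthesis at −0.58 (−0.99 to −0.51 against single controls). Fatty acid uptake at −0.50 (−0.71 to −0.36) says less, as that list shares Lpl with the macrophage list. Such a loss stays open, as lipid droplets at −0.28 (−0.43 to −0.08), adipocyte identity, endothelial genes at −0.42 (−1.02 to 0.02) and progenitors at −0.18 (−0.35 to 0.11) varied with the control. Which cells express the cholesterol synthesis and fatty acid uptake lists was not tested. An effect of the knockout also stays open as a hypothesis, beside other differences between the animals that were not tested, and the lists' calls were lost with an estimated correlation (adjusted p = 0.812).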

How the results depend on the processing

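The tests chosen only after the result was seen were the robust fit, both marker covariates, leaving out the libraries with most muscle counts, control 2 as the only WAT control, all alternatives for the lists of the tissue difference and of BAT against WAT, and leaving out libraries for the overlap. Of single values of genes under all alternatives, 972 kept their direction and side of the threshold, 202 lost and 8 gained a call, and 28 with no call changed sign. The 972 include genes not called in the main fit, which had no call to lose. Of the lost calls, 30 fell in WAT, 100 in BAT and 72 on the tissue difference. In WAT, Gm8210, Zfp949 and Gm11868 lost the call in 4 of 21, 13 of 21 and 13 of 19 alternatives. In BAT, losses ran from 4 of 19 for Kng1 to 14 of 19 for Klf10. For the difference they ran from 1 of 26 for Klf11 and Ier5 to 11 of 26 for Icam1. Of list values, 596 kept both, 180 lost the call and 4 turned in the direction of the test. All 190 values of genes named for BAT against WAT kept both. The cause of the changes below was not tested, apart from fits with fewer samples or fewer genes. Depth limits low genes. Ucp1 in WAT did not pass the count filter, with counts of 255, 9 and 89 in the AKO libraries and 5, 0 and 9 in the controls. That result thus also reflects the spread between AKO libraries. The AKO effect on Ucp1 in WAT is given from the fit with no filter.

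In WAT, 3 genes passed. The count was 446 at an adjusted p under 0.1, 277 with no filter, 1618 with DESeq2, 1 with voom, 5 from FPKM with a pseudocount of 1, 13 at a mean FPKM of at least 1, 1030 with all 12 libraries in 1 fit, 17 with the robust fit, and 0 each without the libraries with most muscle counts, with the B lymphocyte covariate and with control 2 as the only control. Leaving out 1 library gave 1 to 1649. Mcu in WAT passed with DESeq2 (−0.75), with all 12 libraries (−0.73) and without control 2 (−0.76), and ran from −0.85 to −0.69 with 1 library left out. In BAT, 11 genes passed. The count was 33 with no filter, 7 at a mean of at least 2 CPM, 265 with DESeq2, 7 from FPKM with a pseudocount of 0.1, 2 without the libraries with most muscle counts, and 0 to 95 with 1 library left out. Mcu in BAT passed with no filter (−1.27), DESeq2 (−1.28) and all 12 libraries (−1.30), and ran from −1.57 to −1.11 with 1 library left out.

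For the difference between tissues, 45 genes passed. The count was 329 at an adjusted p under 0.1, 132 with no filter, 941 with DESeq2, 24 with voom, 99, 86 and 112 from FPKM with a pseudocount of 1, 0.1 and at a mean FPKM of at least 1, 21 with the muscle covariate, 0 without the libraries with most muscle counts, 10 with the B lymphocyte covariate, 24 with control 2 as the only WAT control, and 2 to 923 with 1 library left out. For BAT against WAT, 7524 genes passed. The count was 4196 with a threshold of 2-fold, 4763 without WAT control 1 and BAT control 1, and 5940 to 7085 with 1 library left out. Those libraries held the most muscle counts of their own groups. With FPKM the median log2 fold change of all genes was −0.25, −0.37 and −0.28, against −0.04 with counts. The overlap of 2 was 34 with DESeq2, 273 at an unadjusted p under 0.05, and 0 to 5 with 1 library left out.

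For the lists, an estimated correlation called 0 in each of the 4 comparisons, and fry 0 in WAT, BAT and the tissue difference but 33 for BAT against WAT (18 higher and 15 lower). With 1 library left out the lists called were 8 to 15 in WAT, 5 to 14 in BAT, 8 to 16 for the tissue difference and 19 to 24 for BAT against WAT. In WAT 14 were called without control 3 and 15 without AKO 2, in BAT 7 without control 2 and 5 without AKO 3. For the tissue difference, 4 were called with the B lymphocyte covariate and 4 with control 2 as the only WAT control, where camera's direction for the T and NK list turned while its median, near 0, kept its sign (−0.0404). For the BAT muscle list, camera's direction turned without AKO 2, where the median changed sign, and with the muscle covariate, where it did not (0.0217), with medians of −1.19 to 8.87 with 1 library left out. The inflammatory list of BAT against WAT changed direction and sign without BAT control 1, with medians of −1.17 to 0.322 with 1 library left out. The B lymphocyte covariate was not run for BAT against WAT.

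Within a tissue, libraries of the same number mostly did not deviate together. The correlations were −0.476, −0.0167 and 0.226 in WAT and −0.616, −0.294 and 0.117 in BAT. No control library correlated best with its own number. With the replicate block, 0 genes were called in WAT and 1 in BAT, and 9 and 10 lists. For the difference between tissues the block gave 261 genes, and for BAT against WAT 8132. There it ended no call of a named gene or list.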

Other observations

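The tests chosen only after the result was seen were the values of the p53 target list, those of the pseudogenes and their parents, that of the genes beside Adipoq, and the second measure of liver transcripts. A list of genes activated by p53, the DNA damage response factor, was written after some members had been seen, so its values are given with no test of the list. In WAT it had a median of 0.49 with 23 of 30 genes positive, in BAT of −0.45 with 21 of 28 negative, and for the difference between tissues of −1.21 with 27 of 30 negative. Without control 2 the medians were 0.26 in WAT and −0.74 in BAT, and the difference had −0.93 without WAT control 2 and −1.31 without BAT control 2. Bbc3, Pidd1 and Pmaip1, which act in cell death, were called over all genes for the difference. Control 2 stood apart from the other controls in both tissues for some members, such as Cdkn1a and Bax, picked after their values were seen. It did not for others, such as Btg2 in the BAT controls (56.4, 65.6 and 61.2 CPM). Cdkn1a, the cell cycle inhibitor p21, measured 489, 87.3 and 386 CPM in the WAT controls and 549, 42.5 and 485 in the BAT controls, against 334, 372 and 250 in WAT AKO and 45.8, 39.3 and 35.1 in BAT AKO. Bax, a pore-forming death effector, measured 29.9, 14.9 and 29.4 CPM in the WAT controls and 29, 13.8 and 30.1 in the BAT controls, against 57.5, 44.2 and 71.8 in WAT AKO and 10.6, 7.94 and 9.12 in BAT AKO.

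Processed pseudogenes formed the first pattern: Gm8210, Gm11868, Gm7049 and Tma7-ps were higher in AKO libraries of both tissues by at least 2-fold at an unadjusted p under 0.05, of 381 tested in both. Their closest coding genes, Rpl29, Cyb5r4, Me1 and Tma7, all lie on chromosome 9 between 86581371 and 109082587, which was seen before the stretch was tested. Zfp949, called in WAT, lies in this stretch too (88548020 to 88571061). Higher expression of the parents is argued against by their median log2 fold change of −0.39 over both tissues. A hypothesis is that AKO mice may carry a strain variant of this stretch whose reads match the pseudogene copies better: of 152 coding genes there, the 4 parents left out, 7 differed in the same direction in both tissues at an unadjusted p under 0.05, against 248 of 12358 elsewhere (odds ratio 2.36, Fisher's exact p = 0.0361). That test leaves it open, since without Zfp949, seen before, 6 of 151 remained (odds ratio 2.02, Fisher's exact p = 0.132), 5 of 136 stretches with as many genes held as many such genes, and the reads were not analysed here.

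Genes beside Adipoq on chromosome 16 formed the second pattern: Kng1, which ends 64.5 kb away, rose in BAT. In WAT it had only 0, 11 and 0 counts in controls and 15, 1 and 0 in AKO, with no clear rise. Kng2, which ends 117 kb away, measured 0.11 in BAT (adjusted p = 0.786 in edgeR's test). Eif4a2, an RNA helicase of translation initiation, measured 1.04 in WAT and 0.73 in BAT. Rfc4 measured 0.89 and 0.73, its exons overlapping those of Eif4a2, while St6gal1 measured 0.96 and −0.03 and Adipoq itself −0.40 and 0.18. Liver RNA, rich in Kng1, was tested by albumin, which reached at most 0.373 of the Kng1 level in a BAT AKO library and so did not stay under the bound of 0.1 set beforehand; by the second measure, 0 of 15 liver transcripts rose by as much as the lowest Kng1 level of 11.1 CPM. A hypothesis is that AKO mice could carry extra copies of this segment, for example within a transgene; the 3 genes within 100 kb that were tested in both tissues had a median of 0.81, reached by 36 of 13797 runs of 3 neighbouring genes (0.261%). As the segment was chosen because Kng1, Eif4a2 and Rfc4 were seen to be higher, this restates the pattern and leaves the hypothesis untested, the labels do not state the Cre driver, and DNA was not analysed here.

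Other splits of the libraries were counted for the remaining results. With 3 libraries per group there are 10 splits, too few for a share under 0.05. In WAT, 1 of 10 called as many genes (3, at most 0 in the others) and 8 of 10 as many lists (8, up to 23 in another). The lists called in WAT had estimated correlations of 0.174 to 0.873, above the preset 0.01, and with estimated correlations the real split called 0 lists. The other splits were run with the preset correlation only. How far that preset or a structure of the WAT libraries lies behind their calls was not tested. In BAT, 1 of 10 called as many genes (11, at most 0 in the others) and 3 of 10 as many lists (11, up to 12). For BAT against WAT, 1 of 10 called as many genes (7524, at most 0) and 4 of 10 as many lists (22, up to 23), and of the 4 splits that part all 3 pairs, 1 called as many genes. For the overlap of WAT and BAT calls, 1 of the 10 splits that keep both tissues of an animal together shared as many (2, at most 0 in the others), and since no other split of either tissue called a gene, the others had none to share.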
